A study of Bos taurus with 2 samples.

How the data were processed

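The samples were total RNA of spermatozoa from high-fertile and from low-fertile bulls, 1 array each, labelled with Cy3 after oligo-dT priming per the labels' protocols. The groups were taken from the fertility entry of the labels. Both arrays lay on one slide, so no slide effect separates them and none could be tested.

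The deposited scanner tables hold the intensity of each spot on a linear scale. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1 in 1 colour, on an array design with probe positions on build HGSC Btau_3.1, and the processed signal had its background subtracted and its spatial trend removed within each array. The mean and background signals in the deposited tables are intensities without these steps. Feature Extraction is also the tool in the submitters' processing notes, and no normalization between arrays is given in the sources used here. The deposited series matrix holds log2 values: set against the log2 processed signals, they equalled these plus one constant per array (-5.12 for the high-fertile and -5.55 for the low-fertile array, within 0.01 for 98.6% of probes on each), and the medians of their columns were -1.43 and -1.37. Their scale and lack of gene centring are thus known from the values, and their direction is that of expression. The 75th percentiles of the columns were -0.0015 on the high-fertile and -0.0018 on the low-fertile array. The matrix values thus amount to nearly the same scaling as the 75th percentile over all probes, and the 2 are not independent alternatives.

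From the processed signals, log2 values were taken per spot, control spots and outlier-flagged spots were left out (2 probes lost), and spots of one probe were averaged. Since 27.6% of probes were well above background on both arrays, less than 50% as the design had set, each array's 75th percentile over those probes was subtracted (148.6 on the high-fertile and 186.3 on the low-fertile array, in linear signal units). The lowest probe signal well above background was 22.6 and 30.3, and no spot was saturated. The array number, 1 per group, limits the precision. A gene's difference was the mean over its probes well above background on both arrays, high-fertile minus low-fertile, and it was counted at an absolute log2 value of at least 1. Where probes of a gene disagree, their SD is given. For a gene well above background on one array only, the bright probe was set against the higher of the lowest well-above-background signal and the dim probe's own value on the other array, written as at least N-fold.

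Probes were named through their accession in the reference table of assembly ARS-UCD2.0 (28110 probes), their symbol (6484), or an older symbol (153), and 16533 kept the name in the file. That table was used for names only. Names in the scanner tables can be old, and 6803 of the 11619 measured gene names are plain symbols. Of the measured genes 1851 had at least 2 measured probes.

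The 22 gene lists, the rule for named genes and 12 alternatives were fixed before the data were examined. The rule named, per direction, the 12 plain-symbol genes with the largest difference, all measured probes of one sign and the dimmer array at least 4 times the lowest well-above-background signal; per direction, the 5 plain-symbol genes on one array only with the largest bound; up to 2 members with the largest positive and 2 with the largest negative difference per list; and 19 genes named always. Some of the last 3 kinds are left out. Other names were chosen after their values were seen, which is said where they stand. The lists cover chromatin condensation, flagellum structure, acrosome and fusion, motility signalling, glycolysis, nuclear oxidative phosphorylation, mitochondrial genes, ribosomal proteins, proteasome, ubiquitin conjugation, chaperones, antioxidants, apoptosis, translation factors, spermatogonia and meiosis, spermatid expression, leukocytes, epithelial and other somatic cells, testis somatic cells, epididymis and accessory glands, erythroid cells, and interferon and inflammation. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 2 arrays; lists with fewer than 5 measured genes have values only.

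The alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), quantile normalization, loess of the difference on mean signal, scaling on the median of detected probes, the 75th percentile over all probes, spike-in scaling, no filter and a stricter filter on dim probes, the brightest probe or the median over probes per gene, the series matrix values, and a 4-fold threshold. Added after seeing the data were leaving out spots in patches, subtracting the median difference of blocks of 32 rows by 20 columns of spots, subtracting the trend on probe GC content, leaving out probes that share 16 bases with probes of at least 3 other genes, and counting only genes with at least 2 probes that each differ 2-fold. A patch is where the median log2 ratio of mean signals over 5 by 5 spots departs by over 0.4 from the array-wide median, with a margin of 1 spot; 291 spots in 7 patches met this. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

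The steps were tested on simulated data for this comparison, with 200 of 11619 genes changed and noise as between spots. Of 100 genes changed by 1.5 on the log2 scale 98.0% were counted, and of 100 changed by 2.5, 100% were counted, while 2 of 11348 unchanged genes were counted. A list shifted by -0.2 fell at percentile 0 of random lists, and 0 of 19 other lists fell in the lowest or highest 2.5% of random lists. The simulation gave all probes of a gene the same change and held no patches and no GC trend between the arrays. On the real arrays non-overlapping probes of one gene had an SD of 0.43 in their differences. The simulated rates therefore do not carry over to the real arrays.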

Results

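Total RNA of spermatozoa from high-fertile and from low-fertile HF crossbred breeding bulls was measured on 2 bovine oligonucleotide arrays, 1 array per fertility group. Each array carried 61657 spots other than controls, for 51280 probes and 31910 gene names. On the high-fertile array 33.2% of these spots were well above background, and on the low-fertile array 32.9%. Both arrays measured 14154 probes (27.6%), which stood for 11619 gene names. The labels speak of bulls in the plural and give no number of animals per array. With 1 array per group no difference had a replicate check, so no p-value is given, and a difference describes these 2 arrays.

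The comparison asked which sperm transcripts differed between bulls of high and low fertility. Most genes had similar levels on both arrays, and 218 of the 11619 genes were at least 2-fold higher and 284 at least 2-fold lower in the high-fertile array. PRM1, the protamine that packs DNA in the sperm head, was 2.14-fold lower in the high-fertile array (log2 difference -1.10, SD 0.28 over 2 probes). TNP2, a transition protein that precedes the protamines on spermatid chromatin, was 2.34-fold higher (log2 1.22, 1 of its 2 probes). Its signal on the low-fertile array was 38.2, near the lowest well-above-background signal there, 30.3. The signal of PRM1 on the high-fertile array was 81.7. Both PRM1 and TNP2 were too dim for the stricter filter on dim probes, so neither was measured or counted there. The ribosomal protein RPS4Y1 was 2.70-fold lower (log2 -1.43, SD 0.17 over 2 probes), its paralog RPS4X differed by -0.94 (SD 0.36 over 5 probes), and whether the probes of RPS4Y1 also bind RPS4X was not tested. The histone variant H2AJ was 2.75-fold higher (log2 1.46, 1 probe with 2 spots that gave 1.57 and 1.35). With normexp background correction PRM1 stood at -0.67 and TNP2 at 0.64, with spike-in scaling TNP2 stood at 0.63 and H2AJ at 0.86, and PRM1 stood at -0.995 with the 75th percentile over all probes and at -0.99 with the series matrix values, all less than 2-fold.

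The rule fixed before the data were examined named the 12 largest differences per direction. Of these 24 names 10 were at least 2-fold apart with no filter on dim probes, 18 with normexp and 18 with spike-in scaling. With the GC trend subtracted, a choice made after seeing the data, 21 were. With no filter, a gene whose probes on the array were all measured keeps its value by construction. Among the 10 names kept there, only SLC25A1 had an unmeasured probe, and its measured spot lay in a patch. The stricter filter, the brightest probe and the series matrix values each kept 22. The median over probes and the 75th percentile over all probes each kept 23. For the stricter filter, the brightest probe and the median over probes this was largely fixed in advance. The rule had already set the dimmer array to at least 4 times the lowest well-above-background signal. A gene with 1 measured probe keeps its value under these 3 choices, and only RPS4Y1, CHRDL1 and RPL37 had more. Among those higher in the high-fertile array were the secretoglobin SCGB2A2 (3.95-fold), KIAA1609 (3.43-fold), the forkhead factor FOXR1 (3.39-fold), the scavenger receptor SCARA3 (3.32-fold), the cadherin CDH12 (2.66-fold), TMEM106A (2.61-fold), CCDC71 (2.60-fold), the calcium channel subunit CACNA1I (2.56-fold) and SHISAL1 (2.53-fold). Lower in the high-fertile array were CNST (2.69-fold, with 3 of the 8 spots around its own at least 2-fold the same way, next to the spots of CREBZF and KCNMB3 described with the genes on one array), TTYH2 (2.30-fold), the actin-binding profilin PFN3 (2.26-fold), the zinc finger gene ZNF836 (2.23-fold), the kinase CDK11B (2.21-fold), the BMP antagonist CHRDL1 (2.17-fold), the phospholipid transporter ATP8B4 (2.16-fold), SLITRK4 (2.15-fold) and the ribosomal protein RPL37 (2.13-fold, SD 0.37 on the log2 scale over 3 probes). The spots of CCDC71 differed by 1.75 and 1.01, those of SHISAL1 by 1.45 and 1.23, and those of CDK11B by -1.14 and -1.15, all on the log2 scale. The 2 measured probes of CHRDL1 had an SD of 0.73, and CHRDL1 stood at -0.60 with the stricter filter and with the brightest probe. SCGB2A2, KIAA1609, FOXR1, SCARA3, CDH12, TMEM106A, CACNA1I, CNST, TTYH2, PFN3, ZNF836, ATP8B4 and SLITRK4 each rested on 1 spot of 1 probe. These genes thus have no spread of their own. Of SCARA3, CDH12 and SLITRK4, 1 of 3 probes was measured. Of SCGB2A2, CACNA1I, CNST, TTYH2, PFN3, CDK11B and ATP8B4 it was 1 of 2, and of CHRDL1 2 of 4. With no filter, where the dim probes count too, all of these names fell below 2-fold. SCGB2A2 then stood at 0.94, CDH12 at 0.41, CDK11B at -0.63 and PFN3 at -0.33. The remaining 4 of the 24 names, MOG (6.56-fold) and SHFL (3.09-fold) on the higher side and SLC25A1 (5.50-fold) and ABCC3 (3.58-fold) on the lower side, each rested on a spot inside a patch of the array where neighbouring spots differed together. On build HGSC Btau_3.1, per the file headers, the probe of SCGB2A2 lies on chromosome 29 from 42392357 to 42392416, that of SCARA3 on chromosome 8 from 11219725 to 11219784, that of H2AJ on chromosome 5 from 102087424 to 102087483, the first of PRM1 on chromosome 25 from 10966344 to 10966403, that of TNP2 on chromosome 25 from 10987920 to 10987973, and the first of RPS4Y1 on chromosome 23 from 10765806 to 10765865.

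**Figure D1:**
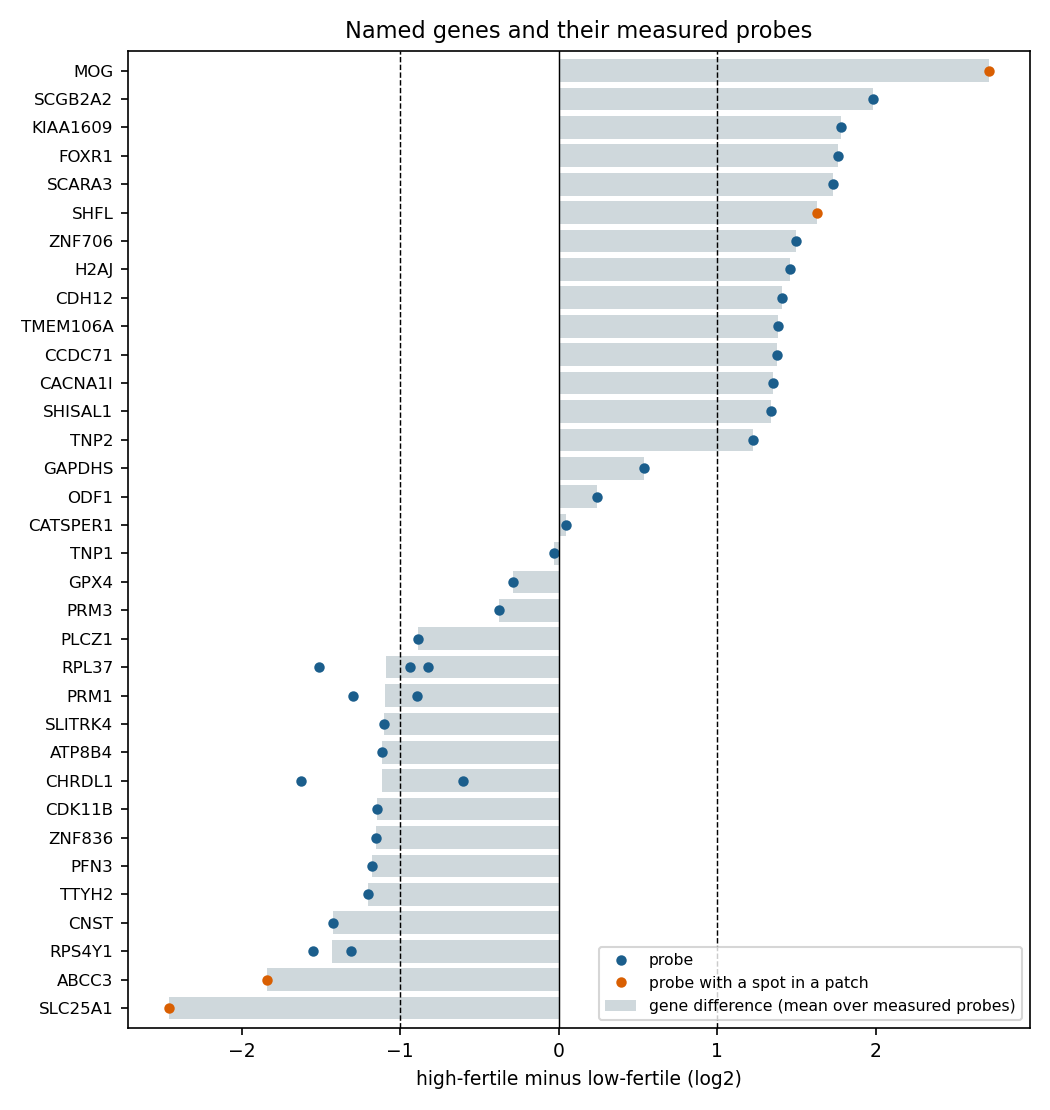
Log2 difference between the high-fertile and the low-fertile array for the genes named by size and the sperm genes that were always named (bars, mean over measured probes), with each measured probe as a point and dashed lines at -1 and 1. MOG, SHFL, SLC25A1 and ABCC3 rest on probes with a spot in a patch, and the 2 probes of PRM1 both lie below 0.

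**Figure D2:**
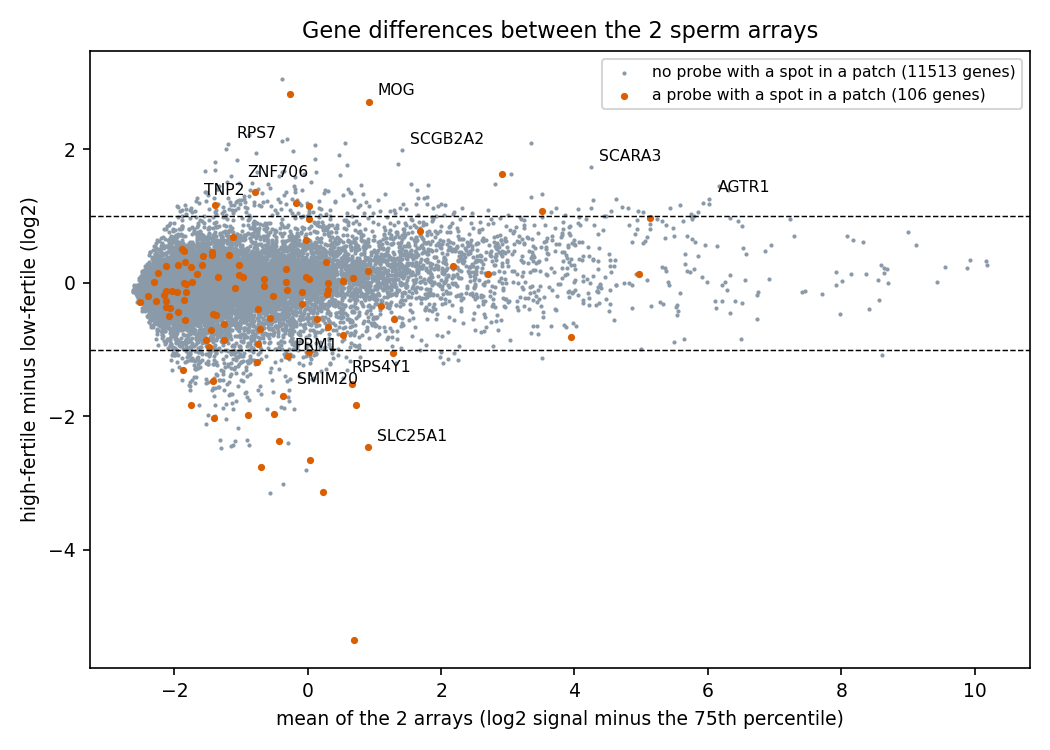
Log2 difference against mean normalized log2 signal for the 11619 genes measured on both arrays, with genes that have a probe spot inside a patch in orange and dashed lines at -1 and 1. Orange points make up 106 genes and include MOG and SLC25A1.

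Over probes with at least 2 spots, the spread between spots was smaller than these differences. The spread between probes of one gene was wider. The difference between the arrays varied between the 2 spots of one probe with an SD of 0.28 on the log2 scale (3038 probes), and with an SD of 0.19 over the 10 measured probes with 4 spots. Within an array the SD between spots of 4-spot probes was 0.13 on the high-fertile and 0.18 on the low-fertile array. The 7 spike-in probes well above background on both arrays were brighter on the high-fertile array by 0.27 on the log2 scale before scaling (SD 0.09), while the median measured probe was dimmer there by 1.26-fold. Scaling on the spike-ins therefore set the median gene at -0.60 and gave 33 genes higher and 1787 lower, a share of 1.81% higher against 43.4% in the scaling used here. With the 75th percentile taken over all probes the counts were 295 and 203 (59.2% higher). The deposited matrix values, nearly the same scaling, gave 297 and 201 (59.6%), and normexp background correction gave 72 and 48. Non-overlapping probes of one gene had an SD of 0.43 in their differences. For 69 genes whose first probe differed at least 2-fold, a second probe that did not overlap it differed in the same direction in 46 and by at least 2-fold in 8.

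Genes of sperm chromatin went both ways. Of 9 measured genes of chromatin condensation, 1 was at least 2-fold higher (TNP2) and 1 at least 2-fold lower (PRM1), and the list median was 0.00, at the 47.9th percentile of random lists of like expression. TNP1 differed by -0.03 and PRM3 by -0.38 on the log2 scale, the linker histone H1FNT by 0.25 and the replacement histone H3-3B by -0.39 (SD 0.35 over 4 probes). The probes of PRM2 were not well above background on either array. With the stricter filter on dim probes 4 genes of the list were measured, of which 0 were 2-fold higher and 0 were 2-fold lower.

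Of 15 measured genes of flagellum structure none differed 2-fold, with a median of 0.14 (94.2nd percentile). The axonemal genes CCDC40 and DNAH3 differed by 0.50 and 0.33, RSPH9 by -0.41, and ODF1, an outer dense fibre protein of the tail, by 0.24. Of 18 measured genes of motility signalling, 1, the adenylate kinase AK7, was at least 2-fold higher (log2 1.14, 1 of 4 probes), with a list median of 0.10 (93.3rd percentile). The kinase GSK3A differed by 0.83, and CATSPER1, of the sperm calcium channel, by 0.05. Of 11 measured genes of the acrosome and gamete fusion, 1, the actin-like ACTL7B, was at least 2-fold higher (log2 1.19), with a list median of 0.11 (89.9th percentile), while PLCZ1, the sperm phospholipase that starts calcium oscillations in the egg, differed by -0.89. The list of spermatid expression, 8 genes measured, had a median of 0.09 (81.4th percentile). CRISP2, AKAP4, IZUMO1, LDHC, PGK2, HSPA2 and PDE3B were not well above background on either array, and the name ADCY10 was not found among the probes. ZNF706, a zinc finger gene, was 2.82-fold higher (1 of 2 probes). These calls ended with normexp and with spike-in scaling, where ACTL7B stood at 0.80 and 0.59, AK7 at 0.51 and 0.54, and ZNF706 at 0.78 and 0.90, and with no filter on dim probes for AK7 (0.77) and ZNF706 (0.66). The signal of AK7 on the low-fertile array, 32.5, lay near the lowest well-above-background signal there, 30.3.

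Ribosomal protein genes stood apart from random lists in the direction of lower levels in the high-fertile array. Of 73 measured, 48 were lower and 25 higher, with a median of -0.15 against a median of 0.10 for random lists of like expression, and 0 of the 10000 random lists had a median as low. The sizes were small: 2 genes were at least 2-fold lower, RPL37 (log2 -1.09) and RPL26 (log2 -1.01, 1 probe), and 2 at least 2-fold higher, RPS7 (log2 2.08, 1 of 2 probes) and RPL18 (log2 1.60, SD 1.18 over 2 probes). With normexp, with the 75th percentile over all probes and with the series matrix values the counts were 2 higher and 0 lower, with spike-in scaling 2 and 25, and with the stricter filter 0 and 1. RPL18 stood at 0.77 with the brightest probe. The signal of RPS7 on the low-fertile array, 39.6, lay near the lowest well-above-background signal there, 30.3. The list median was below 0 under each scaling tried, from -0.75 with spike-ins to -0.04 with the deposited matrix values, and the list median relative to all genes, -0.15, shrank to -0.029 with no filter on dim probes and to -0.045 with the brightest probe per gene. Among 20 lists with a percentile, this was the 1 list within the lowest or highest 2.5% of random lists, where 1 is the number chance gives. Under alternatives other lists lay there too: flagellum structure (98.4th percentile) and proteasome (2.35th) with normexp, oxidative phosphorylation (99.5th) with no filter on dim probes, and glycolysis (100th, 6 genes measured) with the stricter filter.

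Translation factors (26 measured, median -0.15, 3.37th percentile) and proteasome subunits (17 measured, median -0.21, 3.20th percentile) had no member 2-fold different in the scaling and filter used here. Proteasome subunits lay at the 19.2nd percentile with the GC trend subtracted and at the 28.4th with no filter on dim probes, and translation factors at the 24.9th with normexp and at the 35.3rd with no filter. EIF4B differed by -0.91 (SD 0.04 over 3 probes), EIF3D, whose probe has a spot in a patch, by -0.86, EIF2S3 by 0.71, PSMB6 by -0.61, PSMA2 by -0.58 and PSMD8 by 0.65. Of 54 measured nuclear genes of oxidative phosphorylation, 3 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.04 (63.0th percentile). With normexp 0 were higher and 0 lower, and with spike-in scaling 0 higher and 9 lower. Complex I subunit NDUFV3 (log2 1.41) and COX6C (log2 1.23) were among the higher, and ATP5MC3 (log2 -1.18) and COX7A2 (log2 -1.09, SD 0.21 over 3 probes) among the lower. Of 17 glycolysis genes, LDHA was at least 2-fold lower (log2 -1.09, 1 of 3 probes), LDHB differed by 0.64 (SD 0.01 over 2 probes) and the sperm form GAPDHS by 0.54, with a list median of 0.04 (74.5th percentile). LDHA was less than 2-fold lower with normexp (-0.38), quantile normalization (-0.99), the 75th percentile over all probes (-0.98), the series matrix values (-0.98) and the GC trend subtracted (-0.97). Its signal on the high-fertile array, 25.4, lay near the lowest well-above-background signal there, 22.6. With the stricter filter 6 glycolysis genes were measured, of which 1 was at least 2-fold higher and 0 were lower. The mitochondrial genes ND1 and ND5, 2 measured, differed by -0.09 and -0.20.

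Antioxidant genes (22 measured) had a median of -0.06 (27.9th percentile), with PRDX6 at -0.92, GPX4 at -0.29 and KEAP1 at 0.71. The signal of PRDX6 on the high-fertile array, 26.1, lay near the lowest well-above-background signal there, 22.6. Apoptosis genes (17 measured) had a median of -0.18 (6.35th percentile), with TNFRSF10D at -0.81 (SD 0.34 over 4 probes). Chaperones (21 measured) had a median of 0.13 (91.3rd percentile), with BAG3 at 0.54 and HSPA4 at -0.66. Of 25 genes of ubiquitin conjugation, UBE2N was at least 2-fold higher (log2 1.04), RBX1 differed by -0.80, and the median was 0.01 (48.7th percentile). UBE2N was less than 2-fold higher with normexp (0.77), quantile normalization (0.96), loess (0.95), spike-in scaling (0.44), no filter on dim probes (0.46) and grid blocks centred (0.99).

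Marker lists of other cell types all lay within the range of random lists. The list medians were 0.09 for leukocytes (26 measured, 76.4th percentile), 0.05 for epithelial and other somatic cells (28 measured, 72.7th percentile), -0.04 for testis somatic cells (12 measured, 43.4th percentile), -0.09 for epididymis and accessory glands (7 measured, 36.7th percentile), 0.03 for erythroid cells (5 measured, 49.6th percentile) and 0.06 for interferon response and inflammation (14 measured, 78.6th percentile). No gene of these 6 lists differed 2-fold in the scaling and filter used here. ITGB2 differed by 0.61 and PTPRC, the common leukocyte antigen, by -0.51. Of the genes of spermatogonia and meiosis 3 were measured, with differences between 0.02 and 0.24.

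**Figure D3:**
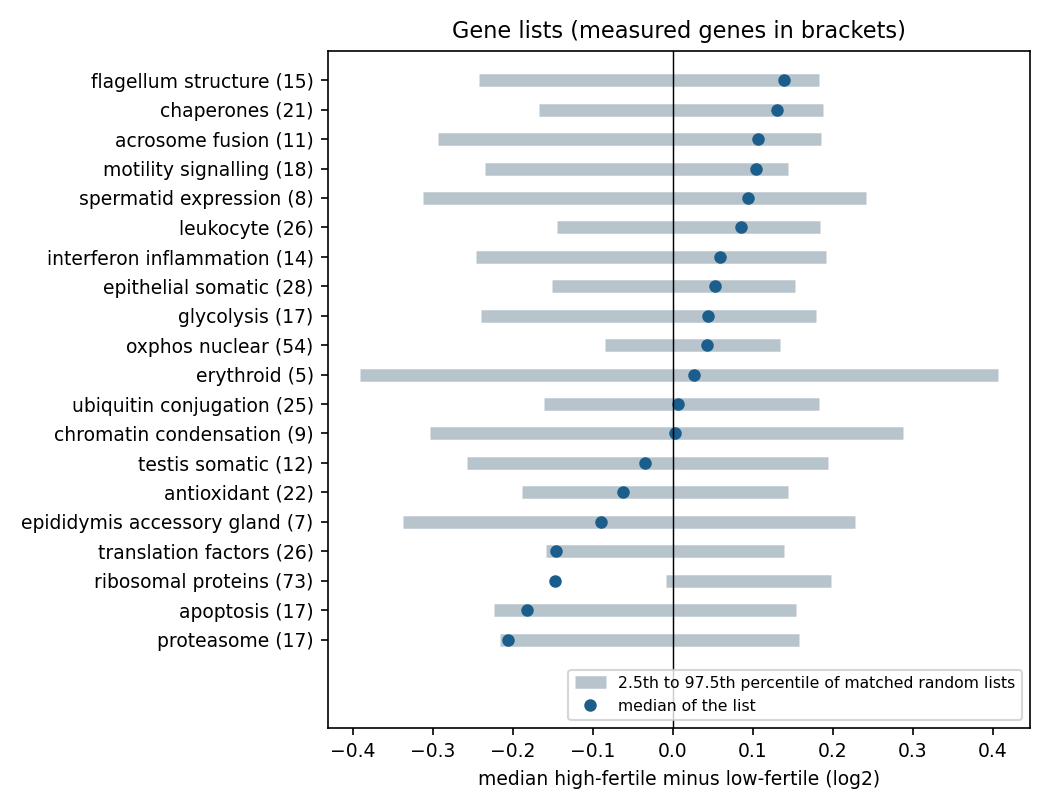
Median log2 difference between the high-fertile and the low-fertile array for each gene list with at least 5 measured genes (points), over the range of 10000 random lists of like expression without the lowest and highest 2.5% (bars). The ribosomal protein list, at -0.15, is the point outside its bar, which runs from -0.01 to 0.20.

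Genes measured on one array only came next. Of 1136 such genes on the high-fertile array 83 were at least 2-fold above the bound of the other array, and of 1196 on the low-fertile array 212. The 10 names with the largest bounds were NCOA5 (at least 122-fold), GPSM2, NRSN1, PHGR1 and DCP2 on the high-fertile array, and C2H2orf62 (at least 110-fold), PROM1, FH, SNU13 and HOXA4 on the low-fertile array. The bright spot of each of these 10 genes lay in a patch. Without patch spots, a choice made after seeing the data, the counts were 62 and 183, and the rule named other genes. On the high-fertile array these were RTN1 (at least 9.78-fold), PHOSPHO2 (at least 4.84-fold), FRMD1 (at least 4.69-fold), BEX3 (at least 4.44-fold) and ABCF2 (at least 4.31-fold). On the low-fertile array they were CREBZF (at least 15.7-fold), KCNMB3 (at least 11.3-fold), GUCY2C (at least 9.25-fold), TMEM177 (at least 8.37-fold) and DCDC1 (at least 7.58-fold). The spots of CREBZF and KCNMB3 are neighbours of each other and of the spot of CNST, and the spots of FOXR1 and CDH12 are neighbours. At least 2-fold the same way were 5 of the 8 spots around CREBZF, 5 of the 8 around KCNMB3, 4 of the 8 around GUCY2C, 3 of the 8 around TMEM177 and 3 of the 8 around CNST. The patch rule did not take in these spots, so their values are not free of the possibility of a local mark.

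**Figure D4:**
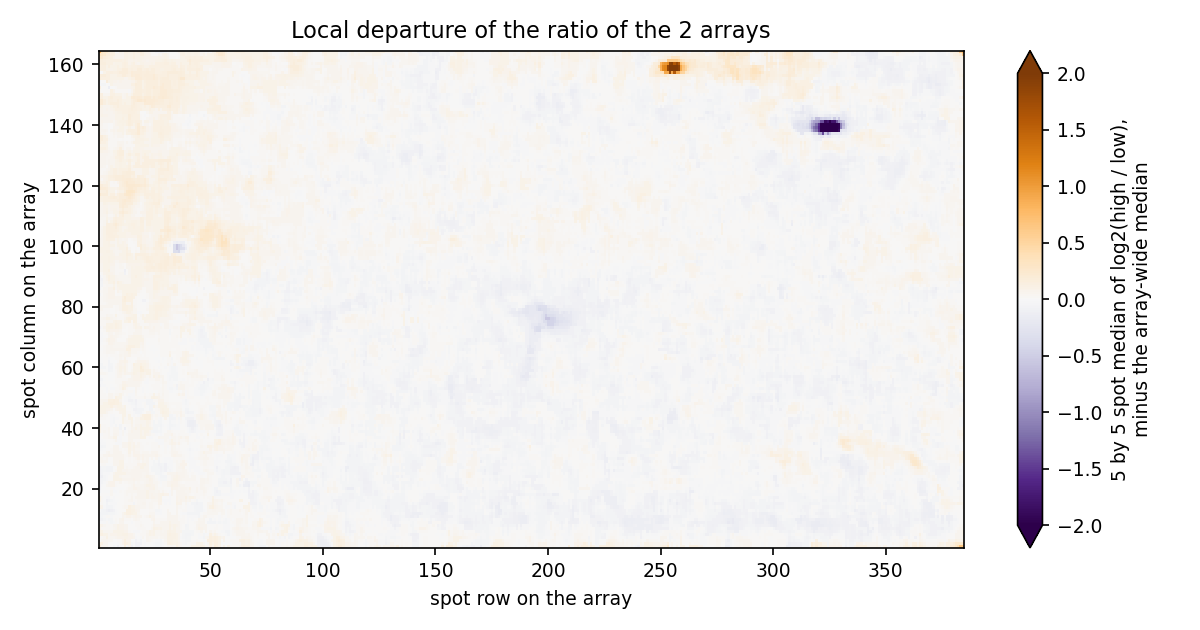
Median over 5 by 5 spots of the log2 ratio of the mean signals of the 2 arrays, minus the array-wide median, by spot row and column (colour). A patch brighter on the low-fertile array covers rows 315 to 332 and columns 136 to 143, and one brighter on the high-fertile array covers rows 248 to 262 and columns 156 to 162.

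For the genes measured on both arrays, leaving out patch spots gave 207 higher and 269 lower of 11587. Of the 24 names fixed by size, 20 remained named then. METTL1 (2.51-fold) and ZNF618 (2.51-fold, 2 spots at 1.36 and 1.30) joined the higher side, and KLHL28 (2.13-fold) and S1PR2 (2.12-fold) the lower side.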

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

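Alternatives marked as added were chosen after seeing the data, and the cause of the changes below was not tested unless stated. Normexp as used here adds an offset of 50 to each signal, which by its construction shrinks the log2 differences of dim genes. Its lower counts and ended calls are therefore in part built in, and how large that part is was not tested. The counts of genes at least 2-fold higher and lower, 218 and 284, became 72 and 48 with normexp, 33 and 1787 with spike-in scaling, which shifts the median gene by its construction to -0.60, 786 and 1752 with no filter on dim probes, which lets in 31910 genes, 125 and 46 with the stricter filter, which leaves 4257 genes, 11 and 21 at 4-fold, and 6 and 10 (added) when at least 2 probes outside patches had to differ 2-fold each. The counts of genes on one array only, 83 and 212, became 21 and 39 with normexp, 31 and 857 with spike-ins, and 22 and 51 at 4-fold; other filters and probe rules do not bear on them. The remaining alternatives kept each count within 1.5 times. The median gene moved to 0.10 with the 75th percentile over all probes and with the series matrix, which are nearly the same scaling. The rest of this paragraph gives list medians relative to all genes. With normexp ribosomal proteins stood at -0.086, proteasome at -0.087, apoptosis at -0.052 and translation factors at -0.031. With no filter on dim probes they were -0.049 for motility signalling, 0.19 for oxidative phosphorylation, -0.029 for ribosomal proteins (0.1th percentile), -0.047 for proteasome, 0.026 for chaperones, 0.063 for antioxidants, -0.0055 for translation factors, 0.097 for testis somatic cells and 0.091 for epididymis and accessory glands. With the stricter filter they were 0.24 for motility signalling, 0.52 for glycolysis, -0.053 for oxidative phosphorylation, -0.11 for proteasome, -0.14 for ubiquitin conjugation, -0.40 for apoptosis, -0.22 for translation factors, -0.0029 for leukocytes, -0.031 for epithelial cells and 0.075 for epididymis and accessory glands. With the brightest probe they were 0.20 for glycolysis, -0.045 for ribosomal proteins and -0.069 for translation factors, with the median over probes -0.21 for ribosomal proteins, with quantile normalization 0.036 for chaperones, and with the GC trend subtracted (added) -0.073 for ribosomal proteins and -0.097 for proteasome. The ribosomal list stayed below the 2.5th percentile under every alternative that gave it a value. Of 38 named genes at least 2-fold apart, 20 stayed at least 2-fold apart with normexp, 25 with spike-ins and 19 with no filter, and 34 were still measured without patch spots. With no filter, the named genes whose probes on the array were all measured could not move. Each of the 38 kept its sign wherever it was measured. The changes of scaling constant could not turn a sign, since they shift all genes alike by at most 0.60, less than the threshold of 1. No replicate could be left out, and no paired analysis was possible because each group has 1 array. Signal over background limits the rest: 27.6% of probes were well above background on both arrays.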

Other observations

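The gene groups in this paragraph and the next, the tests on patch spots, on position and on spot noise, and the settings without patch spots, with the GC trend subtracted and without repeat-sharing probes were chosen after the data were seen. Without patch spots, 1845 genes had at least 2 measured probes, and in 6 of them every probe was at least 2-fold higher and in 10 every probe at least 2-fold lower in the high-fertile array. When the values were shuffled 100 times, the mean counts were 0.57 higher and 1.0 lower, with maxima of 4 and 5. Genes whose probes overlap were included, so the excess does not measure agreement of independent probes. It also does not bear on whether bulls of the 2 fertility groups differ. Higher were LOC510988, which the files name GIMAP7 after a GTPase of immune cells (2.99-fold, SD 0.39 over 2 probes), LOC511617 (2.83-fold), AGTR1, an angiotensin receptor (2.39-fold, SD 0.20 over 4 probes), the globin gene HBZ (2.12-fold, SD 0.08 over 2 probes), MFSD6 (2.47-fold) and LOC615589 (2.17-fold, SD 0.07 over 5 probes). The marker lists of leukocytes and erythroid cells hold neither GIMAP7 nor HBZ. Lower were LOC751805 (3.41-fold), LOC100138905 (2.72-fold), TC433016 (2.34-fold), a gene with an Ensembl name (2.24-fold), SMIM20, an assembly factor of cytochrome oxidase (3.06-fold, SD 0.07 over 2 probes), YPEL5 (2.63-fold), the oocyte gene ZAR1 (2.56-fold), AHCY, which breaks down adenosylhomocysteine (2.32-fold), FAM171A1 (2.27-fold) and RPS4Y1 (2.70-fold).

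Of 30 terms searched in the probe descriptions, 3 gave a median in the lowest and 1 in the highest 2.5% of random lists. The term actin was limited to whole words after a looser match, which also took in other words, had been seen to lie in the highest 2.5%; its 49 genes had a median of 0.06 (90.9th percentile). Olfactory receptor genes, 276 measured, had a median of -0.14 with 190 lower and 86 higher in the high-fertile array. Genes with a histone cluster or a named histone in their description, 42 measured, had a median of -0.15 with 28 lower, and H2AJ, which was higher, was not among them because its description did not match. Defensins, 14 measured, had a median of -0.35 with 13 lower. Homeobox genes, 102 measured, had a median of 0.15 with 62 higher. After the trend on GC content was subtracted, the homeobox genes lay at the 94.1st percentile, the olfactory receptors at the 0.26th, the histones at the 0.20th, the defensins at the 0.09th and the actin genes at the 98.3rd, and the microRNA genes went from the 94.5th to the 1.68th. Of 7 measured probes for clones described as mitochondrial 16S ribosomal RNA, 4 were at least 2-fold lower in the high-fertile array, the lowest at -3.14, while the brightest differed by 0.11. The 3 probes of the 12S kind differed by -0.40 to 0.08. The brightest probes often held sequence shared between genes: 27 of the 50 brightest shared 16 bases with probes of at least 3 other genes, against 256 of the 36280 dimmest (0.71%). Without such probes, 21 of the 24 names fixed by size and 35 of the 38 named genes at least 2-fold apart were still measured. The others rest only on probes that share sequence in this way.

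The largest differences sat close together on the arrays: 3 of the 6 measured probes with 8-fold differences lay in patches, which held 0.50% of measured probes. For 41 probes with a patch spot at least 4-fold apart and another spot elsewhere, the patch spots had a median size of 4.58 on the log2 scale. Their spots outside the patches, turned to the same direction, had a median of -0.10, and 7.32% of these probes were at least 2-fold the same way there. This argues against a difference between the fertility groups for these probes as a set. Local marks on the glass are a candidate explanation that has the values it needs, while MOG, SHFL, SLC25A1 and ABCC3 are each measured by a single spot, and the 23 probes outside the patches for the 14 named genes in patches, with a median of -0.09 turned to the direction of the patch spot, were not well above background on both arrays.

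Ribosomal protein genes were lower in the high-fertile array as a list. Probe differences correlated with GC content (Pearson r 0.22 across probes, which are not independent replicates), and measured ribosomal protein probes had a median GC content of 43.3% against 45% for all. The rise was not steady. Median differences were 0.34 under 35% GC (35 probes), -0.11 both at 40 to 45% and at 45 to 50%, and 0.18 from 60%. The 2 median GC contents alone therefore point to no shift. After that trend was subtracted the list relative to all genes went from -0.15 to -0.073 and lay at the 0.185th percentile, so GC content can account for part of the shift and not for the whole. With patch spots out and grid blocks centred the list was at percentile 0.0, which argues against position on the array. A difference between the fertility groups, and RNA quality or labelling of the single array, cannot be told apart, because the value that would decide is the number of arrays per group, 1.

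Probes of one gene often disagreed. The differences of 2 non-overlapping probes of a gene correlated with r = 0.24 over 1469 genes, across genes that are not independent replicates, against 0.73 for 219 pairs of overlapping probes. Spot noise alone is argued against, since 2 spots of one probe correlated at 0.66. Leaving out repeat-sharing probes gave 0.24 and subtracting the GC trend 0.20, where a rise by over 0.1 was needed, so neither was the whole cause. With the GC trend subtracted the correlation fell, which argues against that trend as a part of the disagreement. No biological explanation, such as transcript forms that differ between probes, was tested, and binding of other transcripts to a probe stays open.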
